A study of Schizosaccharomyces pombe with 7 samples.

How the data were processed

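H3K9me2 ChIP-chip was carried out in the fission yeast Schizosaccharomyces pombe on custom 2-colour Agilent tiling arrays of 60-mer probes placed every 300 bp. Cells were grown in rich medium at 30 °C and fixed with 3% paraformaldehyde, and chromatin was sheared to 500 to 1000 bp per the labels. ChIP and whole-cell extract DNA had been amplified by random-primed PCR. ChIP DNA carried Cy5 and whole-cell extract DNA carried Cy3 on all 7 arrays, and no dye was swapped. For Fft3-GFP the cells were held at 18 °C for 6 h before fixation and treated with 10 mM dimethyl adipimidate afterwards. WT was hybridised in series 1, 2 and 3, fft3∆ in series 2 and 3, and UV21 in series 1, while Fft3-GFP was hybridised once.

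The scanner files of all 7 arrays were used. Per the file headers, the raw, background-subtracted and processed signals are each channel's spot intensity, and the processed signal is the background-subtracted intensity multiplied by 1 linear dye factor per channel, with spatial detrending on some arrays. The scanner software's own ratio column is, per the file headers, log10 of red over green. The deposited value table gives for each array the linear ratio of processed Cy5 to processed Cy3, neither log-transformed nor centred. Its correlation with that ratio from the scanner files was 1.0 for every array, and its medians lay between 0.932 and 0.991. The arrays had been read with Agilent Feature Extraction 12.0.3.1 (the 3 arrays of WT series 1, UV21 and WT series 2, and the Fft3-GFP array), 10.7.3.1 (fft3∆ series 2) and 11.5.1.1 (WT and fft3∆ series 3). Per the file headers, Feature Extraction protocol 1105 was used for the 2 arrays of series 3 and protocol 1200 for the rest. Among the H3K9me2 arrays this coincides with the scanner model. It is called the extraction protocol below, and it concerns the reading of the arrays and not the whole-cell extract.

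On the UV21 array, the processed Cy3 signal of 424 probes was 3.00 times (median) what the software's log10 ratio and the background-subtracted signal of the same spots give, and at 3 of them it was about 9 times. These were all 161, 132 and 131 probes in 3 stretches around the centromeres, at 3745801 to 3796201 on chromosome 1, 1594501 to 1653601 on chromosome 2 and 1069201 to 1142701 on chromosome 3. No probe of the other 6 arrays differed in this way, at a tolerance of 0.1 on the log2 scale. The deposited ratios carry the same values. UV21 values over the pericentromeres are therefore given both from the processed signals and from the software's ratio column.

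Values were log2 of processed Cy5 over processed Cy3 minus the array's median. Background and dyes had been corrected by the scanner software, and no loess or quantile step was added because many probes carry ChIP signal. Control spots and non-uniform features were left out, and probes had to be well above background in Cy3 on the 6 H3K9me2 arrays. This kept 33704 of 41551 probes. Non-uniform features made up 12.3% of the probes of WT series 3 and at most 4.66% of those of any other array, and WT series 3 had 3.79% saturated probes where the others had none. The median Cy3 signal was 19.6 to 219 times its local background and the median Cy5 signal 22.8 to 100.4 times.

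Probe positions are printed as the array gives them, and their genome build is not named in the sources used here. Gene names and neighbours came from the assembly ASM294v3. Each chromosome arm was placed on it by the shift that gave the highest correlation between GC content and Cy3 signal (0.245 to 0.293 at that shift, at most 0.125 at shifts clearly away from it). Of 126 stretches of 100 kb, 1 (the left 100 kb of chromosome 2) matched clearly better at another shift and was given its own. Within arms, 200 kb segments deviated from the shift by a median of 50 to 120 bp, and 1 stretch of 100 kb had a correlation of only 0.0573. No coordinate of that assembly is printed. Of 11 mating-type cassette genes listed, 6 were found in the assembly and 4 had probes; all members of the other lists were found, and 11 of 12 Mmi1-target genes and 2 of 4 names for telomere-linked helicases had probes.

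The genome was divided into 2 kb windows with at least 3 probes and into genes with at least 2. All 6 H3K9me2 arrays entered 1 limma fit (lmFit and eBayes, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. UV21 has 1 array, which is assumed to vary like the WT and fft3∆ arrays. For 14 regions and 10 gene lists (24 sets), the probes' mean was taken per array and tested with limma's fry, with adjustment over the 24 sets; camera with an estimated correlation was run beside it. Exact 2-sided permutation tests over arrays cannot go below 0.2 for 3 arrays against 2 (10 arrangements) or 0.5 for 3 against 1 (4 arrangements). The pericentromeres held the probes starting between 3752101 and 3789901 on chromosome 1, 1600201 and 1644901 on chromosome 2, and 1070101 and 1136701 on chromosome 3. The mating-type region held those between 2113201 and 2137801 on chromosome 2. Subtelomeres were the last 50 kb of chromosomes 1 and 2, followed by 50 kb called subtelomere-adjacent, and the last 25 kb of chromosome 3 were taken as its ends. For Fft3-GFP, each set's mean was placed among 10000 random probe sets of the same size matched on Cy3 signal.

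Genes were named by a rule fixed before the data were examined. For each comparison it takes the 10 largest rises and falls among genes that passed with the same direction in each within-series difference, or the 5 largest by value where fewer than 5 passed, and it allows list members. For Fft3-GFP it takes the 10 highest genes. The fits were tested on simulated data in which 200 units carried changes of −3 to 2 on the log2 scale. On 6193 windows the fft3∆ fit recovered 52.5% of changes of −1, 92.5% of −2 and 100% of −3, with 5 false calls. The UV21 fit on 6193 windows recovered 22.5% of changes of −1, 90% of −2 and 97.5% of −3, with 8 false calls. For 4772 genes the shares were 70%, 100% and 100% for fft3∆ with 12 false calls, and 32.5%, 95% and 100% for UV21 with 5. Fry called 10 of 10 simulated sets shifted by −1 and 0 of 40 unchanged ones. The simulated probes were independent of each other, so this does not show how often fry calls unchanged sets of correlated probes. Deviations from the group means showed no positive correlation between WT and fft3∆ arrays of the same series number (r = −0.0013 in series 2 and −0.043 in series 3). The deviations of the 2 fft3∆ arrays mirror each other, so arrays of different series give no separate comparison. Arrays were not paired in the main fit, and the series number as a block was run as an alternative.

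Alternatives fixed before the data were examined were normexp background correction (offset 50, on median spot signals, since the files hold no mean spot signals), the deposited value table, centring on probes outside heterochromatin, scaling to the pericentromeric mean, no filter on dim probes, unique probes only, the series number or the extraction protocol as a block, 1 kb and 5 kb windows, at least 4 probes per gene, the median of the probes, camera, regions shortened by 5 kb, and leaving out each array. Chosen after seeing the data were the software's ratio at the 424 UV21 probes, these probes left out, non-uniform features kept and saturated probes left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.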

Results

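H3K9me2, the histone mark of fission yeast heterochromatin, was measured as the log2 ratio of ChIP to whole-cell extract signal, relative to each array's median. There were 3 WT arrays, 2 arrays of fft3∆ cells and 1 array of UV21, a strain that the labels name without giving its nature. Fft3 is a chromatin remodeller of the Snf2 family, and 1 further array measured Fft3-GFP in otherwise WT cells. UV21 and Fft3-GFP had no replicates, and the number of arrays limits the precision of all values. In whole-cell extract of fft3∆ cells, the 12 probes in fft3 had a Cy3 signal of 0.298% of the array median in series 2 and 0.379% in series 3. The same probes had 54.0% to 82.7% on the other 5 arrays. In fft3∆ only 3 and 5 of the 12 were well above background, and median signal minus background gave 1.99% and 1.12%.

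Comparing fft3∆ with WT asked where H3K9me2 depends on Fft3. Of 6193 windows of 2 kb, 335 were lower and 6 higher in fft3∆ at an adjusted p under 0.05, and the median window changed by −0.11. The lower windows comprised 69 of the 92 in the last 50 kb of chromosomes 1 and 2, 60 of the 98 in the next 50 kb, and 15 of the 21 on the array's pNSU contigs. They also comprised 6 of 31 windows of the mating-type region and the array's separate mating-type contig together, 4 of 45 in the pericentromeres, 0 of 21 at the ends of chromosome 3, and 181 of the 5875 elsewhere. At an unadjusted p under 0.05, limma called 1007 windows lower and 184 higher. Leaving out WT series 1, 2 or 3 left 147, 189 and 146 called windows, of which 0, 0 and 8 were higher. Leaving out either fft3∆ array leaves 1 array in that group and no spread between fft3∆ arrays. Counts from those fits therefore do not show on which array the small number of rises rests.

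The subtelomeres lost most of their signal. The right subtelomere of chromosome 1 fell from 5.48 ± 1.12 (SD, n = 3) to 2.28 ± 0.35 (SD, n = 2), a 9.22-fold decrease (adjusted p = 0.0419 by fry, 0.153 with an estimated correlation). The left subtelomere of chromosome 1 fell from 5.15 ± 0.21 (SD, n = 3) to 3.41 ± 0.49 (SD, n = 2). On chromosome 2 the left subtelomere fell from 3.32 ± 0.30 to 1.41 ± 0.21 and the right one from 3.05 ± 0.39 to 0.99 ± 0.018. For these 3 regions the adjusted p was 0.0168 by fry and 0.144 with an estimated correlation. The adjacent 50 kb changed by −1.16 (1L), −1.98 (1R), −0.93 (2L) and −1.12 (2R), to between −0.06 and 0.45. Their adjusted p was 0.0459 at 1R and 0.0168 at the others by fry, and 0.202 and 0.144 with an estimated correlation. These 8 calls were lost under 7 to 11 of 21 alternatives each. Each was lost without WT series 1, WT series 3 or either fft3∆ array, and the 4 on chromosome 1 also without WT series 2. The differences were then −1.39 to −3.74 at the subtelomeres and −0.85 to −2.28 in the adjacent regions, with adjusted p between 0.0542 and 0.177. The Cy3 signal of whole-cell extract was higher in fft3∆ than the WT mean by 0.71 (1L), 0.81 (1R), 0.52 (2L) and 0.44 (2R) at the subtelomeres, and by 0.09 to 0.26 in the adjacent regions. At the subtelomeres it was higher by 0.22 to 0.32 in series 2 and by 0.73 to 1.64 in series 3. WT series 3 was the lowest WT array here, with −0.98 at 1L and −1.87 at 1R. WT series 1 and 2 had −0.18 and −0.15 at 1L and −0.80 and −0.72 at 1R.

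**Figure D1:**
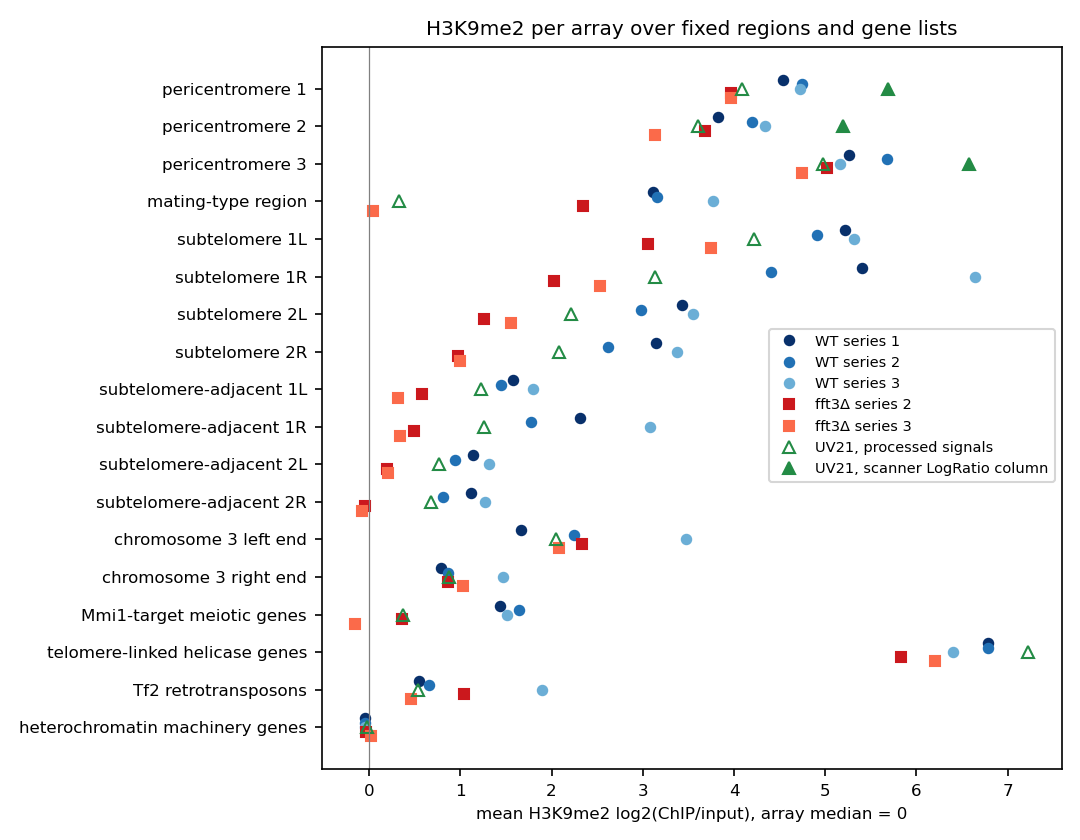
H3K9me2 in regions and gene lists, as mean log2 ratio over the probes of a set relative to the array median. Points are single arrays of WT, fft3∆ and UV21. The right subtelomere of chromosome 1 had a WT mean of 5.48 and a fft3∆ mean of 2.28. At pericentromeres 1, 2 and 3, UV21 had 4.09, 3.61 and 4.97 from the processed signals. From the scanner software's own ratio, UV21 had 5.69, 5.19 and 6.58 there.

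The ratio fell less at the pericentromeres. Pericentromere 1 fell from 4.67 ± 0.12 (SD, n = 3) to 3.97 ± 0.0022 (SD, n = 2), a 1.62-fold decrease (adjusted p = 0.0168 by fry, 0.144 with an estimated correlation). This call was lost under 11 of 19 alternatives, 1 of which, scaling to the pericentromeric mean, removes it by construction, with adjusted p from 0.0150 to 0.610 over all 19. It was lost with normexp (−0.47, adjusted p = 0.226) and without WT series 2 (−0.66, 0.0542), WT series 3 (−0.64, 0.0806), fft3∆ series 2 (−0.70, 0.0657) or fft3∆ series 3 (−0.69, 0.104). Pericentromere 2 differed by −0.72 (adjusted p = 0.138) and pericentromere 3 by −0.48 (adjusted p = 0.156). The Cy3 signal of whole-cell extract over pericentromeres 1 to 3 was higher in fft3∆ than the WT mean by 0.64, 0.67 and 0.66, about the size of these falls. Against the WT array of the same series it was higher by 0.20, 0.21 and 0.09 in series 2 and by 1.40, 1.37 and 1.61 in series 3. WT series 3 stood apart, with Cy3 at −1.57, −1.63 and −1.51 relative to the array median, against −0.46 to −0.78 in WT series 1 and 2. A large part of the rise against the WT mean thus rests on this 1 WT array. The left end of chromosome 3 differed by −0.26 and the right end by −0.09 (adjusted p = 0.839 for both), and both were above 0 when arrays were scaled to their pericentromeric mean (0.08 and 0.06). The pNSU contigs went from 4.06 ± 0.15 to 2.97 ± 0.17, while their Cy3 signal rose by 0.93 (0.39 in series 2 and 1.78 in series 3). Windows beside the pericentromeres were lower over longer stretches: on chromosome 1, 17 windows between 3716001 and 3752000 and 22 between 3790001 and 3836000 had mean changes of −1.34 and −1.27. On chromosome 3, 16 windows between 1026001 and 1070000 and 21 between 1140001 and 1188000 had mean changes of −1.28 and −1.27.

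The 2 fft3∆ arrays differed from each other at the mating-type region, which holds the mating-type genes and their silent copies. Its mean was 3.35 ± 0.37 (SD, n = 3) in WT, and in fft3∆ it was 2.35 in series 2 and 0.04 in series 3 (difference of means −2.15, adjusted p = 0.109). Both were below every WT array, and the differences within series were −0.80 and −3.72. Inside this region, between 2133001 and 2133960, the Cy3 signal of whole-cell extract was missing in fft3∆ series 2 (−6.10 relative to the array median) and WT series 2 (−5.85) and present in fft3∆ series 3 (1.02). The mating-type contig differed by −2.01 and the mating-type cassette genes by −3.05 (adjusted p = 0.229). Of the 2 cassette genes tested, 0 passed in limma over all genes (2 at an unadjusted p under 0.05) and 2 when adjusted over the list alone. At ura4, a uracil-synthesis gene probed at 115501 to 116460 on chromosome 3, WT carried 6.04 ± 0.58. There fft3∆ had 5.14 in series 2 and 2.11 in series 3 (adjusted p = 0.154 by limma). The cassette genes went the same way, with 5.69 ± 0.36 in WT and 5.04 and 0.24 in fft3∆. Probes respond to every copy of their sequence, so the ura4 values do not place the mark at that chromosome 3 position. Without fft3∆ series 2, ura4 (−3.93), mat1-Mc (−5.65) and mat3-Mc (−5.26) passed over all genes. ura4 was named in this comparison after its values were seen.

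Of 4772 genes, 300 were lower and 3 higher in fft3∆ at an adjusted p under 0.05, and 826 and 103 at an unadjusted p under 0.05. Among the lower genes were 44 of 51 in the last 50 kb of chromosomes 1 and 2, and 36 of 54 in the next 50 kb. They also comprised 5 of 9 in the mating-type region and 215 of the 4656 outside the fixed regions. Genes were not filtered on their WT level, so as with the windows not every fall among the 215 can be read as loss of heterochromatin. Leaving out WT series 1, 2 or 3 left 84, 120 and 50 called genes, of which 0, 0 and 1 were higher. Leaving out fft3∆ series 2 gave 668 lower and 99 higher genes, and leaving out fft3∆ series 3 gave 385 and 34. The largest fall was at the pyruvate decarboxylase gene pdc102 (SPAC186.09, chromosome 1, 5548501 to 5549760), from 6.20 ± 0.92 (SD, n = 3) to 1.80 ± 0.39 (SD, n = 2), or 21.2-fold (adjusted p = 0.00566). Its neighbours SPAC186.08c, SPAC186.07c, SPAC186.06, SPAC186.04c and SPAC750.01 changed by −4.19, −4.13, −3.96, −3.61 and −3.93. Of these, SPAC186.08c did not pass without WT series 3, SPAC186.07c without WT series 1 or 3, and SPAC186.06 and SPAC186.04c without either of these or without either fft3∆ array. At other chromosome ends SPAC977.14c (−3.53), SPBC1348.05 (−3.41) and SPBPB2B2.16c (−3.39) were lower, with adjusted p between 0.00520 and 0.00600.

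Away from the ends, the largest fall was at mei4 (SPBC32H8.11, chromosome 2, 1473901 to 1476060), which encodes a meiotic forkhead transcription factor. It went from 4.37 ± 0.29 (SD, n = 3) to 0.73 ± 0.89 (SD, n = 2), or 12.5-fold lower (adjusted p = 0.00520), and passed under each alternative tried. mei4 belongs to the meiotic genes whose transcripts the RNA-binding protein Mmi1 removes. This list fell from 1.53 ± 0.10 to 0.10 ± 0.36, or 2.68-fold (adjusted p = 0.0168 by fry, 0.153 with an estimated correlation). The call of the list was lost under 8 of 21 alternatives, among them leaving out any 1 of the WT or fft3∆ arrays (−1.17 to −1.68, adjusted p between 0.0545 and 0.104). Of its 11 members with values, 5 were lower: mei4, ssm4 (−2.87), mug9 (−2.59), mcp7 (−2.45) and num1, also named mcp5 (−1.70). Adjusted over the list alone, 6 were lower, the sixth being rec8 (−0.57). mug9 and num1 did not pass without WT series 3.

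**Figure D2:**
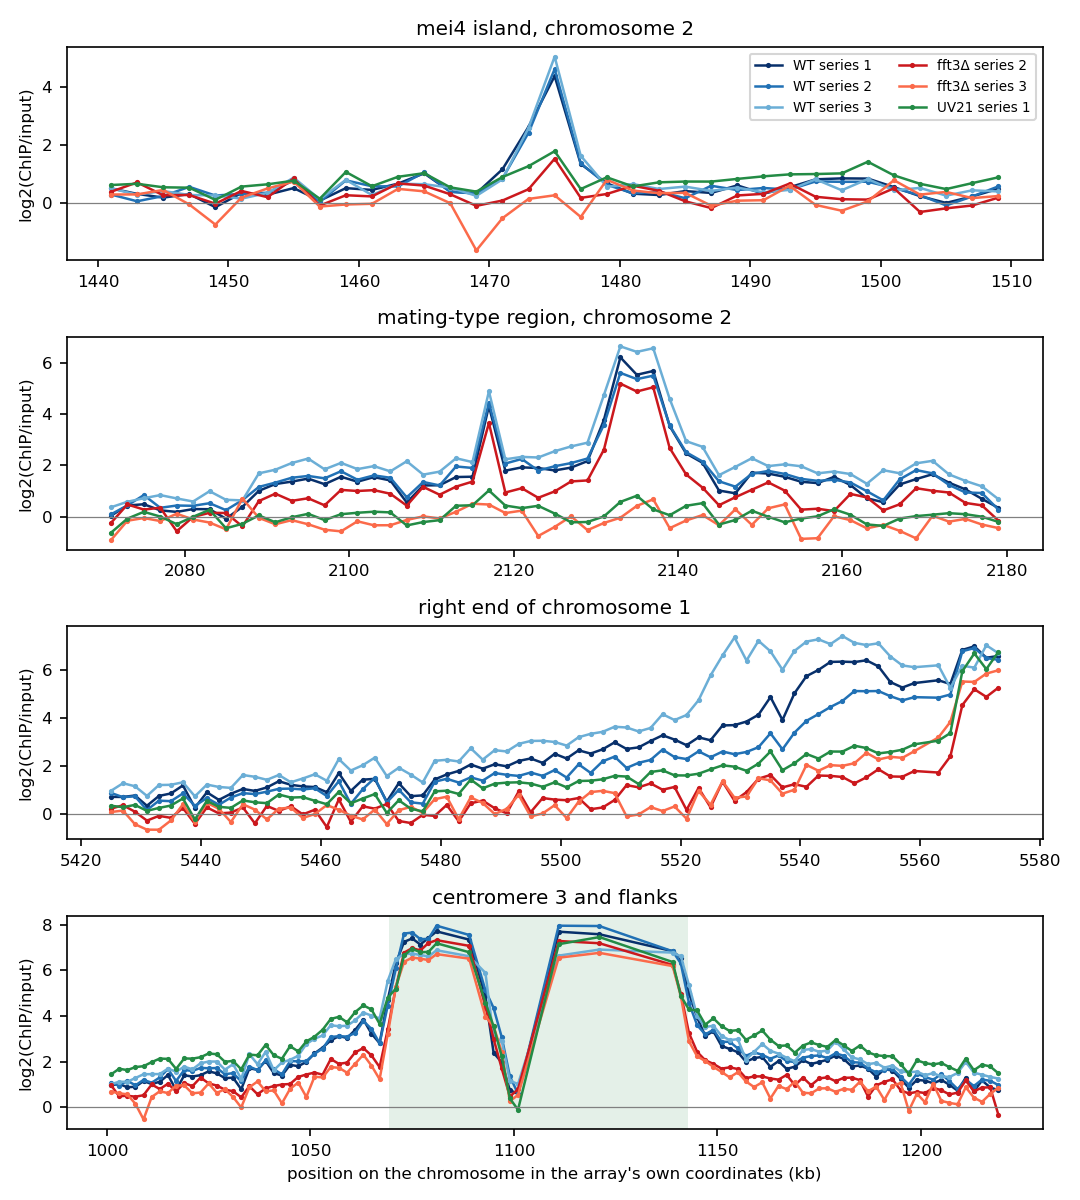
H3K9me2 in 2 kb windows along the mei4 island, the mating-type region, the right end of chromosome 1, and centromere 3 with its flanks, as log2 ratio against array position in kb. Lines are single arrays and bridge windows with too few probes; the shading marks the UV21 probes with a raised processed Cy3 signal, and mei4 had a WT mean of 4.37 and a fft3∆ mean of 0.73.

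The phosphate genes with upstream noncoding RNA fell from 0.78 ± 0.078 to −0.04 ± 0.30 (adjusted p = 0.0334 by fry, 0.153 with an estimated correlation). Of pho1 (−0.96), pho84 (−0.87) and tgp1 (−0.64), 0 passed in limma over all genes (3 at an unadjusted p under 0.05) and 3 when adjusted over the list alone; without fft3∆ series 2, pho1 (−1.56) and pho84 (−1.16) passed over all genes. Housekeeping genes fell from 0.11 ± 0.12 to −0.25 ± 0.053 (adjusted p = 0.0419 by fry, 0.353 with an estimated correlation). Leaving out any 1 of the WT or fft3∆ arrays ended the call of the phosphate list (−0.60 to −1.04, adjusted p between 0.0545 and 0.131) and that of the housekeeping list (−0.31 to −0.42, adjusted p between 0.0644 and 0.177). Among the 12 housekeeping genes fba1 (−1.94) and act1 (−1.14) were lower, 2 over all genes and 2 adjusted over the list alone. act1 adjoins mei4, and fba1 lies within 100 kb of pericentromere 2. act1 did not pass when any 1 of the WT arrays was left out, nor fba1 without WT series 2, WT series 3 or fft3∆ series 3. The telomere-linked helicase list, with probes in tlh1, differed by −0.64 (adjusted p = 0.105), or by 0.28 when scaled to the pericentromeric mean, and tlh1 passed only when adjusted over the list alone (1 of 1). Of the Tf2, histone, heterochromatin machinery and Fun30 family genes, 0 passed in limma over all genes or adjusted over the list alone (0, 3, 1 and 0 at an unadjusted p under 0.05), and tRNA genes were tested only as a set. The differences of these sets were −0.28 for Tf2 retrotransposons (adjusted p = 0.772), −0.37 for histone genes (0.156), −0.42 for tRNA genes (0.280), 0.03 for heterochromatin machinery genes (0.148) and 0.07 for Fun30 family genes (0.157). For the last pair of lists the median gene had the opposite sign, at −0.03 and −0.018. The heterochromatin machinery genes were called higher with normexp (0.08, adjusted p = 0.0161) and with non-uniform features kept (0.03, 0.0307), where their adjusted p ranged from 0.0161 to 0.505 over 21 alternatives. The Fun30 family genes, which include fft3 itself, were called higher without the filter on dim probes (0.72, adjusted p = 0.0150 by fry, range 0.0150 to 0.443). Without that filter the list takes in fft3 probes that lack input DNA in fft3∆, where Cy3 was 0.298% and 0.379% of the array median. Ratios at those probes do not measure H3K9me2.

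Genes higher in fft3∆ were SPAC17A5.19 (1.13, adjusted p = 0.0257), the tRNA dihydrouridine synthase gene dus2 (0.83, adjusted p = 0.0465) and fzr3 (0.67, adjusted p = 0.0482). dus2 and fzr3 were chosen after their values were seen, and SPAC17A5.19 did not pass when any 1 of the WT arrays was left out. The next largest rises by value did not pass: SPAC29A4.23 (1.09, adjusted p = 0.05002), mug35 (1.06, 0.106), ctf8 (1.03, 0.0564) and mrpl32 (0.97, 0.216). Without fft3∆ series 2, SPAC29A4.23 (1.49), mug35 (1.59) and ctf8 (1.39) passed, and without fft3∆ series 3, mrpl32 (1.63) did. SPAC29A4.23 lies in the stretch of chromosome 1 where array and assembly matched least well, so its name is uncertain.

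The extraction protocol of the scanner software differed between series 3 and the other arrays. All 335 lower windows and 300 lower genes were lower within each protocol, on the arrays they had been called on. A fit to the 4 arrays of the protocol of series 1 and 2 alone has 1 residual degree of freedom. Its spread comes from 2 WT arrays only, so its calls are not used as support. The right subtelomere of chromosome 1 differed by −2.88 within the protocol of series 1 and 2 and by −4.11 within that of series 3, pericentromere 1 by −0.67 and −0.76, and the mating-type region by −0.78 and −3.72. With the protocol as a block, 277 windows were called, 250 of them among the 341, and 195 genes, 185 of them also called without the block. In that fit 0 of the 24 sets passed in fry (smallest adjusted p = 0.0501; 12 at an unadjusted p under 0.05). Exact 2-sided permutation over arrays gave p = 0.2 for each of the 12 sets that passed in fry, the smallest that 3 against 2 arrays allows.

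Comparing UV21 with WT asked the same of this strain, with 1 array. No window and no gene passed in limma (smallest adjusted p = 0.264 and 0.146), and 0 of the 24 sets passed in fry (0.250). At an unadjusted p under 0.05, 178 windows were lower and 79 higher, 117 genes were lower and 75 higher, and 3 sets were lower. The exact permutation p cannot go below 0.5 here. Without WT series 2, 6 genes passed. Leaving out either fft3∆ array leaves the spread to the WT arrays alone, so counts from those fits are not used as support.

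By value, the largest difference was at ura4, with 0.85 in UV21 against 6.04 ± 0.58 (SD, n = 3) in WT (36.4-fold lower, adjusted p = 0.214). It was followed by mat1-Mc (−4.95, adjusted p = 0.833), mat3-Mc (−4.83, 0.833), pdc102 (−3.38, 0.192) and SPAC186.08c (−3.37, 0.365). The limma p-values use a spread pooled with the 2 fft3∆ arrays, which differed widely from each other at ura4, mat1-Mc and mat3-Mc. At mat1-Mc the SD was 3.51 in fft3∆ and 0.38 in WT, and at ura4 it was 2.15 and 0.58. UV21 lay below every WT array at these genes, but its single array gives no spread of its own. The mating-type region differed by −3.02, and the cassette genes by −4.89. As in fft3∆, the ura4 values do not place the mark at the probed position on chromosome 3. The subtelomeres differed by −0.93 (1L), −2.35 (1R), −1.10 (2L) and −0.97 (2R), and the adjacent regions by −0.38, −1.12, −0.36 and −0.39. The Cy3 signal of UV21 extract was above the WT mean by 0.67, 0.85, 0.50 and 0.44 at these subtelomeres and by 0.11 to 0.22 in the adjacent regions. It was above by 0.54 at the mating-type region and 1.49 at the cassette genes, so part of these differences may come through the input. The Mmi1-target list differed by −1.15 (adjusted p = 0.250). Adjusted over the list alone, 5 of its genes were lower: mei4 (−2.75), ssm4 (−2.62), mcp7 (−2.07), num1 (−1.61) and mug9 (−1.46). The 2 cassette genes were also lower adjusted over the list alone, and no member of the other lists was. The telomere-linked helicase list differed by 0.57 and the pNSU contigs by 0.50. The largest rises by value were SPBC21B10.15 (0.94), mrpl12 (0.92), lsg1 (0.92), nrf1 (0.88) and fba1 (0.87), which lie near centromeres 2 and 3 (adjusted p between 0.833 and 0.999).

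Over the pericentromeres, the UV21 value depended on the column of the scanner file. From the processed signals, pericentromere 1 differed from WT by −0.58, pericentromere 2 by −0.51 and pericentromere 3 by −0.39. From the scanner software's own ratio, they differed by 1.02 (adjusted p = 0.0530), 1.07 (0.197) and 1.21 (0.167). Normexp on the raw spot signals gave 1.16, 1.25 and 1.36 (adjusted p = 0.126 at pericentromere 1). Over the probes concerned, the background-subtracted Cy3 signal of UV21 was −0.65 relative to the array median and the processed one 0.92, while on the other 5 H3K9me2 arrays the 2 signals differed by less than 0.01.

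The mutants were also set against each other. Across 6193 windows, the UV21 difference in series 1 and the mean fft3∆ difference in series 2 and 3, which share no array, had r = 0.461 (rho = −0.017), where windows are not independent replicates. With the software's ratio r was 0.401, and outside the fixed heterochromatic regions it was −0.013. The fft3∆ differences of series 2 and 3 had r = 0.459. In the direct contrast, limma called 46 windows lower and 0 higher in fft3∆ than in UV21 (642 lower and 96 higher at an unadjusted p under 0.05). Of the 46, 35 lay within 100 kb of a pericentromere (mean difference −1.81) and 10 on the pNSU contigs (−2.07). With the software's ratio 100 were lower, 74 within 100 kb of a pericentromere, 11 on the pNSU contigs and 10 in the pericentromeres.

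Fft3-GFP was measured to ask where Fft3 sits on chromatin, on 1 array without an untagged control. Of the 24 sets, 12 had a mean above the central 95% of random probe sets matched on Cy3 signal. The random sets are scattered single probes, while the probes of a region are neighbours. A set's place relative to them is therefore no test and only describes this array. The highest were the mating-type cassette genes (0.81), Tf2 retrotransposons (0.74), tRNA genes (0.63), telomere-linked helicase genes (0.62), the mating-type region (0.51), histone genes (0.50) and pericentromere 3 (0.45). Housekeeping genes had 0.44, phosphate genes 0.42, pericentromere 2 0.29, the left subtelomere of chromosome 1 0.27 and pericentromere 1 0.25. Below the random sets lay the left and right subtelomeres of chromosome 2 (−0.15 and −0.04), the adjacent region 1R (−0.12) and the heterochromatin machinery genes (−0.13). The Mmi1-target genes (0.08) and Fun30 family genes (−0.0098) lay within them. Outside these sets, the pNSU contigs had 1.05, the mating-type contig 0.53 and the mitochondrial contig −3.02.

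**Figure D3:**
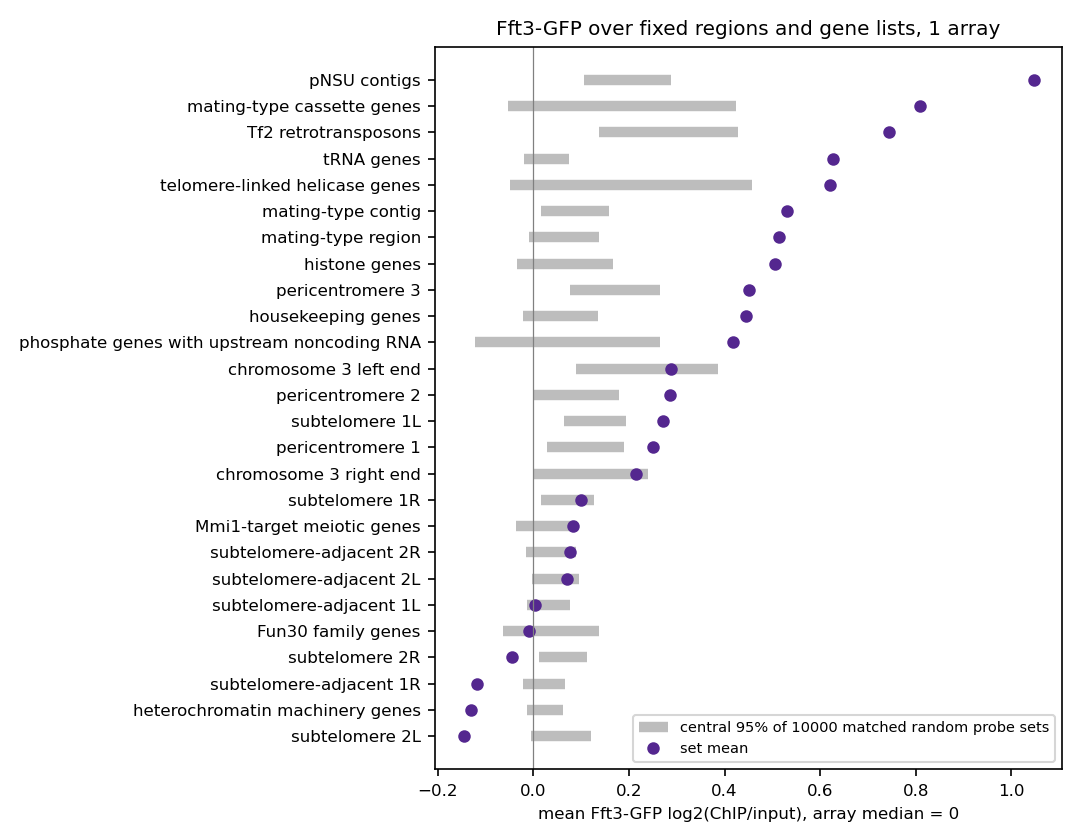
Fft3-GFP in each region and gene list, as mean log2 ratio of ChIP to whole-cell extract over its probes. Points are set means on the 1 array and grey bars the central 95% of 10000 matched random probe sets; tRNA genes had 0.63 and the left subtelomere of chromosome 2 −0.15.

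Of 4953 genes, those with the highest Fft3-GFP were ubi4 (1.29), SPAC212.06c (1.25), tef103 (1.16), sod1 (1.16), knh3 (1.12), act1 (1.12), tef101, tef102, rps27 (1.06) and psu1 (1.02). The 335 windows with lower H3K9me2 in fft3∆ had a mean Fft3-GFP of 0.08 ± 0.37 (SD over windows), and the 5852 windows not called had 0.04 ± 0.26, but the medians lay the other way at −0.01 and 0.0039. Outside the fixed regions the means were 0.05 for called and 0.03 for other windows, well within the spread. Across 6193 windows Fft3-GFP had r = 0.295 (rho = 0.0913) with WT H3K9me2 and r = −0.119 with the change in fft3∆, where windows are not independent replicates.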

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

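The tests in this part were chosen after the results were seen, except those on mating-type DNA in the extract, on the log ratio at matched WT level and on the Cy3 rise as a share of the fall at subtelomeres.

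In the direct comparison of the mutants, 0 of the 24 sets passed with the processed signals (smallest adjusted p = 0.212) and 1 with the scanner software's ratio. The 1 UV21 array is assumed to vary like the arrays of the other groups. With the software's ratio, pericentromere 1 was lower in fft3∆ than in UV21 by −1.72 on the log2 scale (adjusted p = 0.0100 by limma's fry, 0.0339 with an estimated correlation), while pericentromeres 2 and 3 did not pass (0.0960 and 0.0920). With the processed signals the difference at pericentromere 1 was −0.12 (adjusted p = 0.687). The telomere-linked helicase genes were higher in UV21 than the WT mean by 0.57, and both fft3∆ arrays were lower than WT; the direct difference did not pass (adjusted p = 0.212). The pNSU contigs, which belong to none of the 24 sets, were higher in UV21 by 0.50, at a level of 4.57, and lower on both fft3∆ arrays, where the Cy3 signal of the extract had risen. The direct difference there was −1.60, with an unadjusted fry p of 0.00106.

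The level of UV21 over the pericentromeres differed between columns of its scanner file. The column that departs from the spot signals was the processed Cy3. Processed over background-subtracted Cy3 at these probes exceeded that of the array's other probes by 1.58 ± 0.15 (SD over probes) on the log2 scale, which argues against the software's ratio being the altered column. More centromeric DNA in the extract is excluded too, since the background-subtracted Cy3 signal there exceeded the WT mean by only 0.11 ± 0.42 (SD of WT) on the log2 scale. The factor had a median of 3.00 and was about 9 at 3 of the 424 probes, which form unbroken stretches. The pericentromeric values below WT thus came from the raised column alone: the software's ratio (1.02, 1.07 and 1.21) and normexp on the raw signals (1.16, 1.25 and 1.36) both lay above the WT mean, without passing on this 1 array. The sources used here do not say how or why the factor arose, and no further explanation was tested.

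The mating-type region had lost part of its H3K9me2 on the fft3∆ array of series 2 (2.35, −0.80 against WT series 2) and nearly all on that of series 3 (0.04, −3.72 against WT series 3). A lower ChIP efficiency in series 3 does not account for the difference, since the 3 pericentromeres differed between these arrays by only −0.27 ± 0.27 (SD over the 3). Loss of most of the mating-type DNA is argued against, as 77 probes of the region were usable on all 6 H3K9me2 arrays (82 on the Fft3-GFP array). Their Cy3 signal in series 3 was above the WT mean by 0.87 ± 0.24 (SD of WT). Probes that were dim in Cy3 on any array had been left out of that mean, so it cannot show a loss at single places. The silent state may have been lost in more cells of 1 fft3∆ culture than of the other, which 2 fft3∆ arrays cannot decide. The 2 arrays also differed in mating-type DNA: the Cy3 signal between 2133001 and 2133960, inside the region, was missing in fft3∆ series 2 and WT series 2 and present in fft3∆ series 3. A strain difference there stays open. The WT array with the missing stretch differed in H3K9me2 from the mean of the other 2 by −0.29 ± 0.46 (SD of those 2), but it is a single array and carries fft3. The extraction protocol of the scanner software differed between the 2 fft3∆ arrays as well, so strain, software protocol and culture cannot be told apart.

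In fft3∆, H3K9me2 fell further at subtelomeres and islands than at pericentromeres. A common loss of ChIP efficiency is argued against by the excess over the array median, whose log2 ratio to WT was lower at subtelomeres than at pericentromeres by −1.67 in series 2 and −2.07 in series 3. At matched WT levels of 4 to 6, 37 subtelomeric windows changed by a median of −3.04 and 5 pericentromeric ones by −1.49. The difference was −1.56 ± 0.42 (larger interquartile range divided by 2), which argues against compression of high ratios as the whole of the contrast. All 45 pericentromeric windows changed by a median of only −0.50, so a part through compression stays open. Islands were not in this test. A higher Cy3 input signal is argued against as the source of this contrast. Against the WT array of the same series, the Cy3 rise at the 4 subtelomeres exceeded that at the 3 pericentromeres by only 0.12 in series 2 and was smaller in series 3 (−0.31), while the gap between their changes in H3K9me2 was −1.25 and −1.71. At the Mmi1-target genes Cy3 rose by 0.13 and 0.22, less than at the pericentromeres (0.17 and 1.46). For the fall itself at the 8 subtelomeric and adjacent regions, a part through the input stays open: the Cy3 rise came to 22.6 ± 15.7% of it, 13.7% in series 2 and 35.9% in series 3. The share varied from 7.85% at the adjacent region 2R to 40.6% at the left subtelomere of chromosome 1, where it was 87.9% in series 3. At the 3 pericentromeres the Cy3 rise came to 104 ± 112% (SD of the 2 series) of the smaller fall, 25.9% in series 2 and 184% in series 3, and at the pNSU contigs to 84.8 ± 94.0%, 34.9% and 168%. The mean shares and those of series 3 include WT series 3. Its pericentromeric Cy3 signal (−1.51 to −1.63) lay far below that of WT series 1 and 2 (−0.46 to −0.78). Whether these falls of the ratio are a loss of the mark or a rise of the input signal was not decided. A different dependence of these domains on Fft3 stays open, untested.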

How the results depend on the processing

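Replacing or leaving out the raised UV21 probes, keeping non-uniform features and leaving out saturated probes were chosen after seeing the data. The cause of a change was not tested unless stated.

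The 341 windows called in fft3∆ stayed within 1.5 times that count under 12 of 20 alternatives, the called genes under 13 of 19 and the 12 sets under 12 of 21. Some of these alternatives could not change the counts. The deposited table holds the same ratios, and the software's ratio at the UV21 probes leaves the WT and fft3∆ values as they are. The median of the probes changes a set's value but not its p in fry. Scaling to the pericentromeric mean left 157 windows, 171 genes and 7 sets. The series number as a block, which leaves fewer degrees of freedom, gave 222 windows and 0 sets, and the extraction protocol as a block gave 195 genes and 0 sets. Camera with an estimated correlation gave 0 sets. Windows of 1 kb gave 537 calls and windows of 5 kb gave 205, with more and fewer windows tested. Leaving out 1 array at a time gave 146 (without WT series 3) to 796 windows (without fft3∆ series 2), 50 to 767 genes for the same arrays, and 0 to 12 sets.

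The counts of 0 in UV21 held under 16 of 19 alternatives for windows, 13 of 18 for genes and 20 of 20 for sets. Here too the deposited table could not change a count, nor could the median of the probes change that of the sets. Normexp gave 1 window and 12 genes, the series block 43 genes, and leaving out 1 array at a time 0 to 28 windows (28 without fft3∆ series 2) and 0 to 34 genes (34 without fft3∆ series 3). The correlation of UV21 with fft3∆ was kept under 3 of 4 alternatives and was −0.013 outside the fixed regions. The 12 sets with high Fft3-GFP were kept under 4 of 4, among them the deposited table, which holds the same ratios. The mean Cy3 signal of fft3 in fft3∆ was 1.55% of the array median from median signals minus background.

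Some differences changed sign, none of which had passed a test over all genes or sets. With normexp, UV21 had 1.16, 1.25 and 1.36 at pericentromeres 1, 2 and 3, 0.035 at Fun30 family genes and 0.18 at tRNA genes. With the software's ratio at the raised probes, the pericentromeres had 1.02, 1.07 and 1.21 and tRNA genes 0.13, through the Cy3 factor itself. Scaling to the pericentromeric mean gave fft3∆ 0.28 at tlh1 and the telomere-linked helicase list, 0.26 at pericentromere 3 (this scaling balances the pericentromeres by construction), and 0.082 and 0.058 at the left and right ends of chromosome 3, and gave UV21 0.18 at pericentromere 3 and 0.019 at tRNA genes. With unique probes only, the right end of chromosome 3 had 0.056 in fft3∆ and tRNA genes 0.00973 in UV21. With the series block, UV21 had 0.39 and 0.089 at the left and right ends of chromosome 3, 0.047 at Fun30 family genes and 0.077 at tRNA genes. With the protocol block, UV21 had 0.013 at Fun30 family genes and 0.073 at tRNA genes. By the median of the probes, fft3∆ had 0.089 at the right end of chromosome 3 and 0.064 at tRNA genes. Leaving out 1 array at a time gave fft3∆ −0.66 to 0.26 at the left and −0.22 to 0.12 at the right end of chromosome 3 and −0.57 to 0.16 at Tf2 retrotransposons. It gave UV21 −0.81 to 0.094 and −0.30 to 0.047 at these ends, −0.058 to 0.0067 at Fun30 family genes and −0.17 to 0.15 at tRNA genes. The upper ends are the values without WT series 3, and without fft3∆ series 3 Tf2 retrotransposons in fft3∆ had 0.000971. For UV21, tRNA genes had 0.076 with the raised probes left out and 0.0055 with non-uniform features kept.

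Over all reported values, 1551 kept their direction and side of the threshold, 133 lost a call, 49 gained one, 36 changed sign and 12 without a test moved by more than their spread. The values that were kept include those under alternatives that could not change them. The slide as a random block was not run, because only WT series 1 and UV21 share a slide and its correlation could not be estimated. Signal over background was at least 19.6 in both channels of all arrays, and the number of arrays limits the precision.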

Other observations

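All tests in this part were chosen after the results were seen.

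Windows outside the fixed regions that were lower in fft3∆ fell into different kinds in UV21. Islands were windows more than 100 kb from the pericentromeres with a WT level of at least 1 in series 2 and 3 and a fall of at least 1 in both fft3∆ series. The 22 such windows include mei4, ssm4, mcp7 and num1. They also include edges of larger domains, such as windows between 5448001 and 5462000 on chromosome 1. These lie in a lowered stretch that reaches the adjacent region 1R, which itself differed by −1.12 in UV21. Of the 22 windows, 95.5% were lower in UV21 than in WT series 1, with a mean difference of −1.16 ± 0.73 (SD over windows). Of the other 92 windows there with that WT level, 57 were lower in UV21 (mean −0.43 ± 0.83), so that 68.4% of all 114 were (mean −0.57). The 7 windows that fell in fft3∆ from a WT level under 1 had a mean difference of −0.25 in UV21, and 85.7% were lower. Of 49 windows chosen like the islands but within 100 kb of the pericentromeres, only 20.4% were lower in UV21, and their mean difference was 0.29 ± 0.68. The raised processed Cy3 signal of UV21 lowered 12 of these 49; with the software's ratio 4.08% were lower (mean 0.61 ± 0.26), and of the 37 windows without raised probes 0 were (mean 0.63 ± 0.23). UV21 may therefore share the loss of fft3∆ at these 22 windows and not the loss at the flanks. This rests on 1 UV21 array and on windows chosen for their change in fft3∆, some of them at edges of larger domains. Part of the lower values extends to windows that fell less in fft3∆.

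The whole-cell extract signal over the mating-type region was higher on both arrays that had lost H3K9me2 there, UV21 and fft3∆ series 3, than on any WT array, by at least 0.34 on the log2 scale. On the fft3∆ array of series 3 the Cy3 signal was also higher than on any WT array at the 3 pericentromeres, where H3K9me2 changed by only −0.76, −1.21 and −0.41 against WT series 3. On the fft3∆ array of series 2, with a partial loss at the mating-type region, the Cy3 signal there (−0.01) lay within the WT range. Cy3 is the denominator of the ratio that measures the mark, so these values test no link between them.

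The Cy3 signal was lost at further places than fft3. Between 2932501 and 2940360 on chromosome 1 its median lay at −6.77 on the log2 scale in WT series 1 and −7.47 in UV21. It lay at −8.09 in fft3∆ series 2 and −8.45 in fft3∆ series 3, and the stretch was present on the other 3 arrays. Both fft3∆ arrays thus differed here from the WT array of their series (−0.11 in series 2 and −0.22 in series 3). Strain differences other than the deletion of fft3 therefore cannot be told apart from it within series. Between 2133001 and 2133960 on chromosome 2, which is inside the mating-type region, it lay at −5.85 in WT series 2 and −6.10 in fft3∆ series 2, against −2.12 in WT series 3 and at least −0.73 on the other arrays.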
